A study of Mus musculus with 2 samples.

How the data were processed

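Single-nucleus RNA sequencing was used on nuclei isolated from mouse diaphragm, the main muscle of inspiration, with 1 library from control animals and 1 from mechanically ventilated animals. Both were wild type, per the labels. The ventilated animals received pentobarbital into the peritoneal cavity, a tracheostomy, continuous anaesthesia and ventilation at a tidal volume of 10 mL/kg, 150 breaths per min and a positive end-expiratory pressure of 2 cm H2O, with body temperature held near 37 °C, per the series' design text. The design text says of the control animals only that they were not ventilated, so whether they were injected or anaesthetised, how long ventilation lasted and how many animals went into each library are not given in the sources used here. The nuclei were released with a detergent buffer from fresh or frozen tissue and profiled with a droplet 3' kit that attaches a unique molecular identifier (UMI) to each captured RNA, per the labels' protocols.

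The authors deposited, for each library, a matrix of whole-number UMI counts per gene and nucleus, with its gene and barcode lists. Cell Ranger 7.0.1 wrote the matrices, per the file headers, and the genome build was mm10, per the submitters' processing notes. The annotation, the alignment settings and the step that separated nuclei from empty droplets are not given in the sources used here. The control matrix held 8579 barcodes and 31953961 UMIs, with a median of 2947 UMIs and 1568 genes per nucleus. The ventilated matrix held 7226 barcodes and 30293399 UMIs, with medians of 3015 and 1653. The lowest total in either matrix was 500 UMIs.

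From these counts, nuclei with fewer than 300 genes or more than 5% of UMIs from the mitochondrial genome were left out. The gene limit removed none, and the mitochondrial limit 41 control and 13 ventilated nuclei. Doublets were called in each library with Scrublet, as run in scanpy 1.11.5, at an expected rate of 6%. It called 489 control nuclei (5.70%) and 1200 ventilated nuclei (16.6%), an unequal removal that was compared with keeping all called doublets and with leaving out the 6% of nuclei with the highest scores in each library. The analysis kept 8049 control and 6014 ventilated nuclei. Both libraries were clustered together without batch centring, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15).

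Clusters were named from 24 marker lists fixed before the data were examined. A cluster took the name of the list with the highest mean log2(CPM + 5) over the lower quartile of clusters. The minimum score of 1, the gap of 0.5 to the next list and the rule that pan-endothelial markers do not count against a lymphatic endothelial name were set after the clusters were seen. At least 3 markers had to be detected in over 5% of the cluster's nuclei, and no other class could have more markers than the named one among the top 10 genes by fold. Of the 6 lymphatic markers 5 were used, because the symbol of the other is shared by several gene identifiers. These limits kept 1 cluster, led by Chl1, unnamed, and it held 3.35% of control and 6.32% of ventilated nuclei. Markers of neuromuscular and myotendinous junctions and of regenerating myonuclei counted as myofibre, and those of smooth muscle as pericyte. Names are written "like" because they rest on markers alone.

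With 1 library per group there is no replicate check of any difference, so no test, p-value or number of changed genes is given. Counts were summed per class and library and written as CPM, UMIs scaled to a class total of 1000000, with exact 95% Poisson intervals, ratios (ventilated over control) with exact conditional binomial intervals, and shares with exact Clopper-Pearson intervals. All of these cover counting error only, not differences between animals or preparations, and not the clumping of UMIs in a few nuclei. Where a library had 0 UMIs, the fold is a lower bound against a floor of 3 counts per library. Classes with at least 200 nuclei in each library were compared gene by gene. The 34 gene lists were also fixed before the data were examined. A list is described by the median log2 ratio of its members with at least 20 UMIs, by its percentile among 10000 random lists matched on mean expression, which describes these libraries only, and by the number of members at least 1.5-fold higher or lower.

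Genes were named by a rule fixed beforehand. In myofibre-like nuclei these were the 12 higher and 12 lower genes whose 95% interval of the ratio stayed farthest from 1, among genes with at least 50 UMIs and 10 CPM in the higher library and the same direction in nuclei dominated by Myh1. Mitochondrial, ribosomal protein, haemoglobin, predicted and clone genes were left out. In the other compared classes the rule took 5 higher and 5 lower genes. Stat3 was added in every class, with 2 to 4 members per list by the same interval. Cntfr, Trim63, Junb and Bcl6 fell outside the rule and were named after their values were seen. Tpm3, given for macrophage-like nuclei, fell outside the rule too. Some genes that the rule names are not reported here. Gene positions came from GENCODE release M21 on GRCm38, the build also called mm10, matched by gene identifier. For shares of nuclei with a UMI, each nucleus was also thinned to 1000 UMIs and shallower nuclei were left out.

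The ratio and list steps were run on simulated counts drawn from a Poisson distribution, which the intervals also assume. This checks the computation and says nothing about the clumping of UMIs in a few nuclei. In the myofibre-like simulation of 7838 genes, intervals excluded 1 in the right direction for 96.0% of 50 genes raised 1.5-fold and 100% of 50 genes raised 4-fold, and they covered the true ratio for 95.4% of unchanged genes. Of 200 random lists of unchanged genes, 12.5% fell outside the 5th to 95th percentile. Alternatives covered the nucleus filters, the doublet treatment, the clustering resolution, centring within libraries, the scaling, thinning, the minimum UMIs of list members and a pseudocount. The removal of clusters 7 and 8, the equal doublet removal and the list medians outside myofibre-like nuclei were added after the data were seen. The limit on carried-over myofibre RNA in the test of a difference shared by all classes was first set on the median marker (sarcomere value 0.209, below the limit of 0.5) and moved to the upper quartile (1.18) once that was seen. The reason was the view that cytoplasmic markers are carried over more than nuclear ones, which was not tested.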

Results

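The data were gene counts from single nuclei of mouse diaphragm, with 1 control library of 8049 analysed nuclei and 28286817 UMIs and 1 library of ventilated animals with 6014 nuclei and 20070991 UMIs. The series title names the transcription factor Stat3 in connection with diaphragm dysfunction caused by a ventilator, so the comparison asks how the nuclei of the ventilated muscle differed from those of the control muscle and where Stat3 stood among those differences. The difference between the libraries has no replicate check, and the ventilated animals also had an injection, surgery and anaesthesia, which the sources do not say of the control animals either way.

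Myofibre-like nuclei, defined by Ttn, Neb, Trdn and other muscle genes, made up 25.7% of control nuclei (95% interval 24.8 to 26.7, 2072 nuclei) and 12.6% of ventilated nuclei (11.8 to 13.5, 758 nuclei). Mesothelial-like nuclei, which carry markers of the layer that lines the peritoneal and pleural surfaces, were the largest class and stood at 36.5% (35.4 to 37.5) and 54.4% (53.2 to 55.7). Fibro-adipogenic progenitor-like nuclei stood at 8.96% and 3.67%, a ratio of 0.410 that was 0.113 at clustering resolution 2.0, satellite cell-like nuclei at 2.37% and 0.765%, and endothelial-like nuclei at 3.47% and 1.88%, all lower in the ventilated library. B lymphocyte-like nuclei were higher, at 1.5% and 4.82%, as were T or NK lymphocyte-like nuclei at 0.373% and 0.831%. Lymphatic endothelial-like nuclei stood at 12.8% and 9.99%, and macrophage-like nuclei at 3.45% and 3.81%. The remaining classes were small, with pericyte-like nuclei at 0.957% and 0.549% and adipocyte-like nuclei at 0.596% and 0.333%. Among nuclei that were neither mesothelial-like nor unnamed, the myofibre-like share was 42.8% in control and 32.1% in ventilated nuclei. The number of doublets removed differed between the libraries. The 6 mesothelial markers together, Krt19 among them, were themselves lower in ventilated mesothelial-like nuclei (2618 and 1542 CPM, ratio 0.589). The clusters with most ventilated nuclei of this class (19, 20 and 21) had marker scores of 1.90, 1.62 and 1.70. Those with most control nuclei (10, 11 and 12) had 2.77, 2.59 and 2.39.

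**Figure D1:**
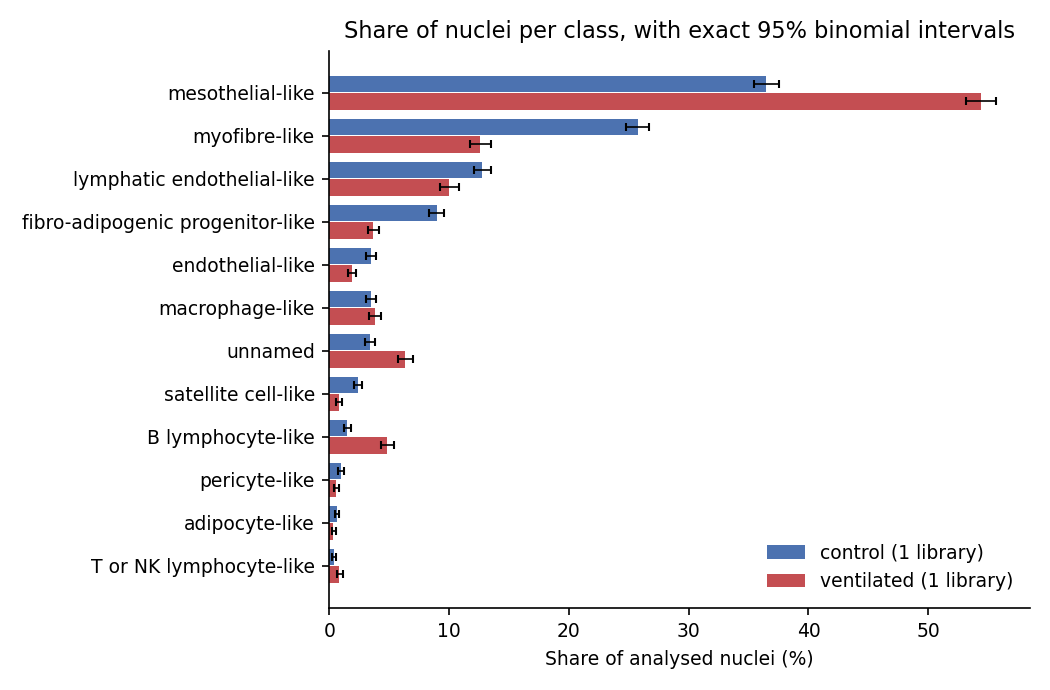
Horizontal bars give the share of analysed nuclei in each class (%), blue for the control library and red for the ventilated library, with exact 95% binomial intervals that cover counting error only. Mesothelial-like nuclei stood at 36.5% and 54.4%, and myofibre-like nuclei at 25.7% and 12.6%.

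Stat3 was higher in the ventilated library in each of the 11 named classes, and the ratio was highest in myofibre-like nuclei. The gene (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540 on the minus strand of GRCm38) encodes a transcription factor that cytokines of the interleukin-6 family activate. In myofibre-like nuclei its level was 151 CPM in control and 755 CPM in ventilated nuclei, a ratio of 5.01 (95% interval 4.72 to 5.32; 1637 and 3080 UMIs). A Stat3 UMI was found in 40.7% of control and 79.2% of ventilated myofibre-like nuclei, at median depths of 4077 and 4131 UMIs. After thinning to 1000 UMIs, which left out 59 and 30 nuclei, the shares were 13.7% (12.2 to 15.2) and 46.7% (43.0 to 50.4). Stat3 is broadly expressed, so no class could serve as one that lacks it. In control nuclei the myofibre-like level was below that of mesothelial-like nuclei (338 CPM), and in ventilated nuclei it was above it (505 CPM).

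In the other classes with at least 200 nuclei per library the Stat3 ratio was 2.11 (1.83 to 2.43) in fibro-adipogenic progenitor-like, 1.86 (1.54 to 2.26) in macrophage-like, 1.49 (1.43 to 1.56) in mesothelial-like and 1.47 (1.32 to 1.63) in lymphatic endothelial-like nuclei. The ratio in fibro-adipogenic progenitor-like nuclei depended on the clustering, with a log2 ratio of 1.07 as reported and 0.20 at resolution 2.0. Satellite cell-like, adipocyte-like and pericyte-like nuclei, with few nuclei each, had ratios of 3.01 (2.05 to 4.4), 3.05 (2.13 to 4.34) and 3.03 (1.91 to 4.82), and endothelial-like nuclei 1.69 (1.28 to 2.21). In B lymphocyte-like and T or NK lymphocyte-like nuclei the intervals of the ratio included 1 (0.943 to 1.67 and 0.735 to 2.18).

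**Figure D2:**
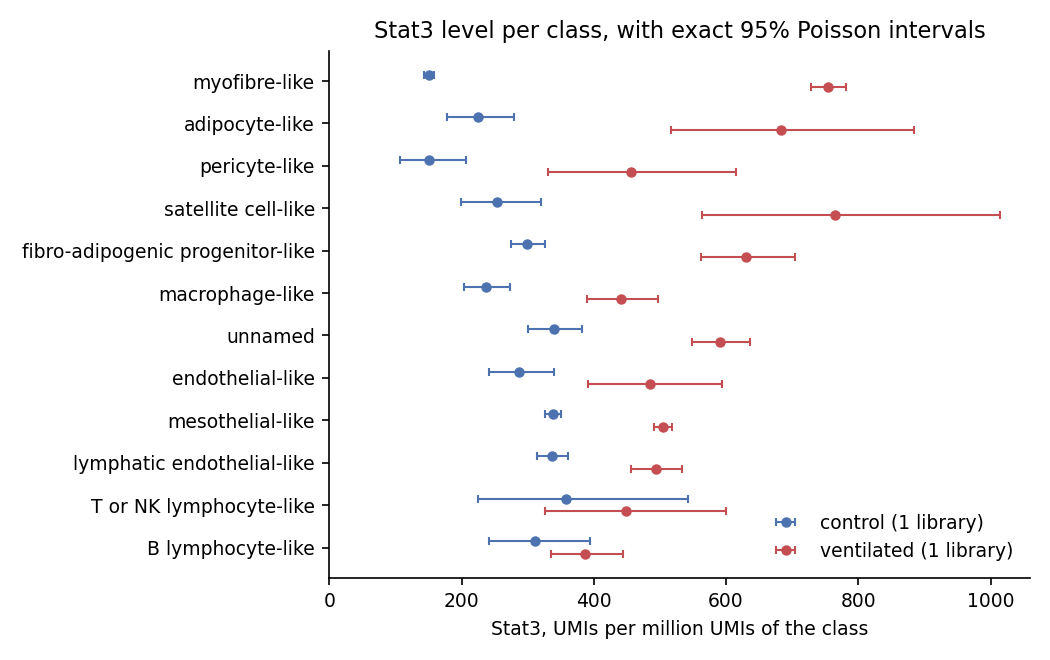
Points give the Stat3 level in each class, in CPM, for the control library (blue) and the ventilated library (red), with exact 95% Poisson intervals that cover counting error only. In myofibre-like nuclei the level was 151 CPM in control and 755 CPM in ventilated nuclei.

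Some genes of cytokine signalling and most measured STAT3 target genes were higher in ventilated myofibre-like nuclei. Among 15 measured genes of JAK-STAT and interleukin-6 family signalling, 7 were at least 1.5-fold higher and 1 lower, with a median log2 ratio of 0.43 (percentile 92.4 of matched lists). Stat2 (8.93 and 80.6 CPM, ratio 9.03) and the oncostatin M receptor Osmr (16.4 and 115 CPM, ratio 7.02) were higher, and the ciliary neurotrophic factor receptor Cntfr was lower (106 and 20.1 CPM, ratio 0.189), and was named after its value was seen as the 1 lower member. Of 15 STAT3 target genes, 10 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 1.92 (percentile 100). They included Socs3, a feedback inhibitor of this pathway (2.21 and 23.8 CPM, ratio 10.8, 6.83 to 17.6), Pim1 (ratio 7.11, 5.92 to 8.58) and Bcl3 (ratio 9.32, 5.74 to 15.7). That median was 0.61 over members with at least 100 UMIs, 1.13 after thinning to 1000 UMIs and 1.09 with a pseudocount of 5 CPM. The excess of the STAT3 target genes over control was 1.53 times (median over members) what RNA of other classes was estimated to give from their markers in these nuclei, and 2.06 and 0.962 times with the lower and upper quartile of the marker estimates. For single genes that value was 0.777 for Bcl3, 1.04 for Stat2, 1.05 for Osmr, 1.60 for Socs3, 2.10 for Pim1, 2.93 for Junb and 4.09 for Bcl6 (ratio 1.36). The estimate adds up classes that share markers, so it can count the same RNA repeatedly, which would make it too high. The median gene of this class had a log2 ratio of 0.21, and list medians are to be read against that value.

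The interferon response list had the highest median of all lists, a log2 ratio of 2.85 (counting interval 2.61 to 3.08, percentile 100), with 19 of 20 measured members at least 1.5-fold higher and 0 lower. Gbp7 stood at 7.09 and 135 CPM (ratio 19.0, 14.9 to 24.4), Ifi44 at 0.552 and 10.5 CPM (ratio 19.1, 8.09 to 54.9), and Rsad2 at 0.920 and 15.9 CPM (ratio 17.3, 8.84 to 37.8). With a pseudocount of 5 CPM the list median was 1.57. In the NF-kappaB and cytokine list 15 of 21 members were higher and 1 lower, with a median of 1.41 (percentile 100); Serpina3n, Saa3 and the chemokine gene Ccl2 (1.29 and 14.5 CPM, ratio 11.2) were among its leading members. Its median was 2.09 with called doublets kept, 2.14 with an equal share of high-scoring nuclei left out and 0.77 with a pseudocount of 5 CPM. Other cell types' markers were present in these nuclei. Some were higher in the ventilated library, with B lymphocyte markers at 53.9 and 182 CPM, T or NK lymphocyte markers at 5.06 and 25.7 CPM and neutrophil markers at 6.35 and 27.5 CPM. Several more abundant ones were lower. Fibro-adipogenic progenitor markers stood at 1105 and 812 CPM, pericyte markers at 285 and 210 CPM and mesothelial markers at 263 and 180 CPM. Macrophage markers stood at 233 and 200 CPM and endothelial markers at 172 and 129 CPM. Ventilated mesothelial-like nuclei also held these transcripts, with Gbp7 at 149 CPM and Rsad2 at 114 CPM. From the markers of the other classes in myofibre-like nuclei, RNA of those classes was estimated to give an excess of the interferon genes of about the size observed (median of observed over estimated excess 1.03), and of the NF-kappaB and cytokine genes a larger one (0.611). Single genes lay on both sides of these medians, with 5.73 for Serpina3n, 2.80 for Gbp7, 0.577 for Rsad2 and 0.401 for Ifi44, and 3 of the 20 interferon genes were above 1.5. With the lower and upper quartile of the marker estimates the interferon median was 1.41 and 0.706, with 7 and 2 genes above 1.5. The NF-kappaB and cytokine median was then 0.819 and 0.392.

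Most sarcomere, calcium-handling and oxidative phosphorylation genes were lower in ventilated myofibre-like nuclei. Of 36 sarcomere genes 26 were at least 1.5-fold lower and 1 higher, with a median log2 ratio of -0.92 (percentile 0). The list was also lower in the other compared classes, with medians from -2.02 to -0.94, where RNA carried over from myofibres was estimated to give 0.209 times its control level with the median marker and 1.18 times with the upper quartile (medians over the 4 classes). Myom2, which encodes a protein of the M-band, stood at 148 and 10.0 CPM (ratio 0.0679, 0.0485 to 0.0925), Mybpc2 at 41.1 and 5.64 CPM (ratio 0.137), and Myh4 at 143 and 21.1 CPM (ratio 0.148). Of 23 calcium-handling genes 15 were lower and 2 higher (median -0.84, percentile 0), among them Casq2 (ratio 0.132, 0.0962 to 0.177) and Jph2 (ratio 0.231). The calcium-handling medians in the other compared classes ran from -0.72 in mesothelial-like to -0.15 in fibro-adipogenic progenitor-like nuclei. In the oxidative phosphorylation list 23 of 36 genes were lower and 0 higher (median -0.62, percentile 0), in the tricarboxylic acid cycle list 5 of 17 were lower and 0 higher (median -0.49), and in the glycolysis and glycogen list 11 of 22 were lower and 1 higher (median -0.72). Hexokinase 2 (Hk2) stood at 1099 and 238 CPM (ratio 0.217, 0.203 to 0.232), the glycogen phosphorylase gene Pygm at 310 and 65.2 CPM (ratio 0.210), Atp5a1 at 221 and 115 CPM (ratio 0.520) and Idh3a at a ratio of 0.40. The share of UMIs from the mitochondrial genome was also lower, at 0.474% and 0.244%, and the haemoglobin share, a sign of blood RNA, was 0.0148% and 0.00267%. Both shares were lower in every other class too, so neither was particular to myofibre-like nuclei. The mitochondrial share was 0.848% and 0.413% in mesothelial-like and 0.474% and 0.234% in macrophage-like nuclei, and closest in pericyte-like ones (0.605% and 0.539%). The ribosomal protein share was close in myofibre-like nuclei, at 0.443% and 0.425%. Of 6 long RNAs that stay in the nucleus 3 were at least 1.5-fold lower and 0 higher (median -0.63), with Rian at a ratio of 0.222 and Malat1 at 0.701.

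Fatty acid genes went the other way. Of 26 genes of fatty acid uptake and oxidation 15 were higher and 1 lower (median 0.97, percentile 100), including Acot1 (0.644 and 11.8 CPM, ratio 18.3), the lipid droplet gene Plin2 (49.2 and 231 CPM, ratio 4.69) and Cpt2 (11.6 and 44.6 CPM, ratio 3.85). Adipocyte markers in these nuclei stood at 34.1 and 69.8 CPM (ratio 2.05, 1.75 to 2.40). The genes of the regulators Ppara (885 and 134 CPM, ratio 0.151, 0.138 to 0.165) and Ppargc1a (1294 and 352 CPM) were lower, in a mitochondrial biogenesis list with a median of -0.12 and 9 of 20 members lower. Oxidative stress defence (16 of 24 higher, 2 lower, median 0.82, percentile 100) included Hmox1 (3.13 and 62.7 CPM, 95% interval of the ratio 14.0 to 29.6) and Cat (55.4 and 259.5 CPM, ratio 4.68). Heat shock proteins (9 of 17 higher, 0 lower, median 0.92, percentile 100) included Hspa1b (137 and 601 CPM, ratio 4.39) and Hspb1 (195 and 620 CPM, ratio 3.18). Without clusters 7 and 8, of which cluster 7 is led by Hspa1a and Hspa1b, the heat shock median was 0.15.

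The 5 lists tied to muscle protein breakdown and cell death had medians of 0.38 to 0.61, with the atrophy marker Fbxo32 (atrogin-1) at 763 and 2515 CPM (ratio 3.30, 3.20 to 3.39) and Trim63 (MuRF1), named after its value was seen, at 700 and 1080 CPM (ratio 1.54, 1.49 to 1.60). Of 16 muscle ubiquitin ligase genes 8 were higher and 3 lower (median 0.54, percentile 99.4), and the 3 lower ones included Asb2 (365 and 32.4 CPM, ratio 0.0885). In the FoxO list 10 of 20 members were higher and 0 lower (median 0.51, percentile 99.1), led by Fbxo32, Gadd45a (ratio 4.03) and Pdk4, which limits the entry of pyruvate into the mitochondrial cycle (1017 and 2714 CPM, ratio 2.67). In the proteasome list 15 of 31 were higher and 0 lower (median 0.55, percentile 99.8), among them Psma3 (ratio 2.10) and Psmd11 (ratio 1.82), and in the autophagy and lysosome list 10 of 28 were higher and 2 lower (median 0.38, percentile 94.3), led by Ulk1 (29.5 and 117 CPM, ratio 3.95). Calpains and cell death genes had a median of 0.61 (8 of 15 higher, 0 lower), with Casp12 at a ratio of 5.59. The proteasome list lay above the median gene in the other compared classes too, with medians from 0.21 in macrophage-like to 0.49 in fibro-adipogenic progenitor-like nuclei. Across those classes the medians were -0.10 to 0.40 for calpains and cell death and 0.03 to 0.31 for ubiquitin ligases. They were -0.29 to 0.39 for FoxO and -0.32 to 0.03 for autophagy and lysosome.

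The glucocorticoid response list had a median of 0.06 (percentile 35.2, 9 of 20 higher, 2 lower) and a mean of 0.64. Among its higher members were Mt2 (ratio 17.1), Mt1 (ratio 4.06) and Angptl4 (ratio 37.9, 14.0 to 144). In the other compared classes the list's median was below 0, from -0.91 in macrophage-like and -0.65 in mesothelial-like to -0.18 in fibro-adipogenic progenitor-like nuclei. Neuromuscular junction and denervation genes had a median of -0.01 and a mean of 0.04, and a median of -0.60 without clusters 7 and 8, with Runx1 (62.8 and 422 CPM, ratio 6.72), known to be induced in denervated muscle, higher and Lrp4 lower (ratio 0.340). Dystrophin complex genes had a median of 0.29 and a mean of -0.06, with Sntb1 higher (ratio 3.38) and Dag1 lower (ratio 0.459). Mechanical load genes (median 0.54, and -0.034 in nuclei dominated by Myh1) held Ankrd1 higher (16.8 and 227 CPM, ratio 13.6) and Tead1 lower (1123 and 468 CPM, ratio 0.416). Immediate early genes had a median of -0.86 (13 of 23 lower, 7 higher), with Fosb (ratio 0.0789) and Nr4a1 (ratio 0.237) lower and Myc higher (ratio 6.21). They were lower in the other compared classes too, with medians from -0.80 in lymphatic endothelial-like to -0.29 in fibro-adipogenic progenitor-like nuclei. Without cluster 7, which is led by stress genes, and cluster 8, the myofibre-like cluster with the highest median UMI counts (7331 and 6935), the median of that list was 0.69. Extracellular matrix genes had a median of -0.34, which was 0.12 with called doublets kept and 0.30 with an equal share of high-scoring nuclei left out.

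**Figure D3:**
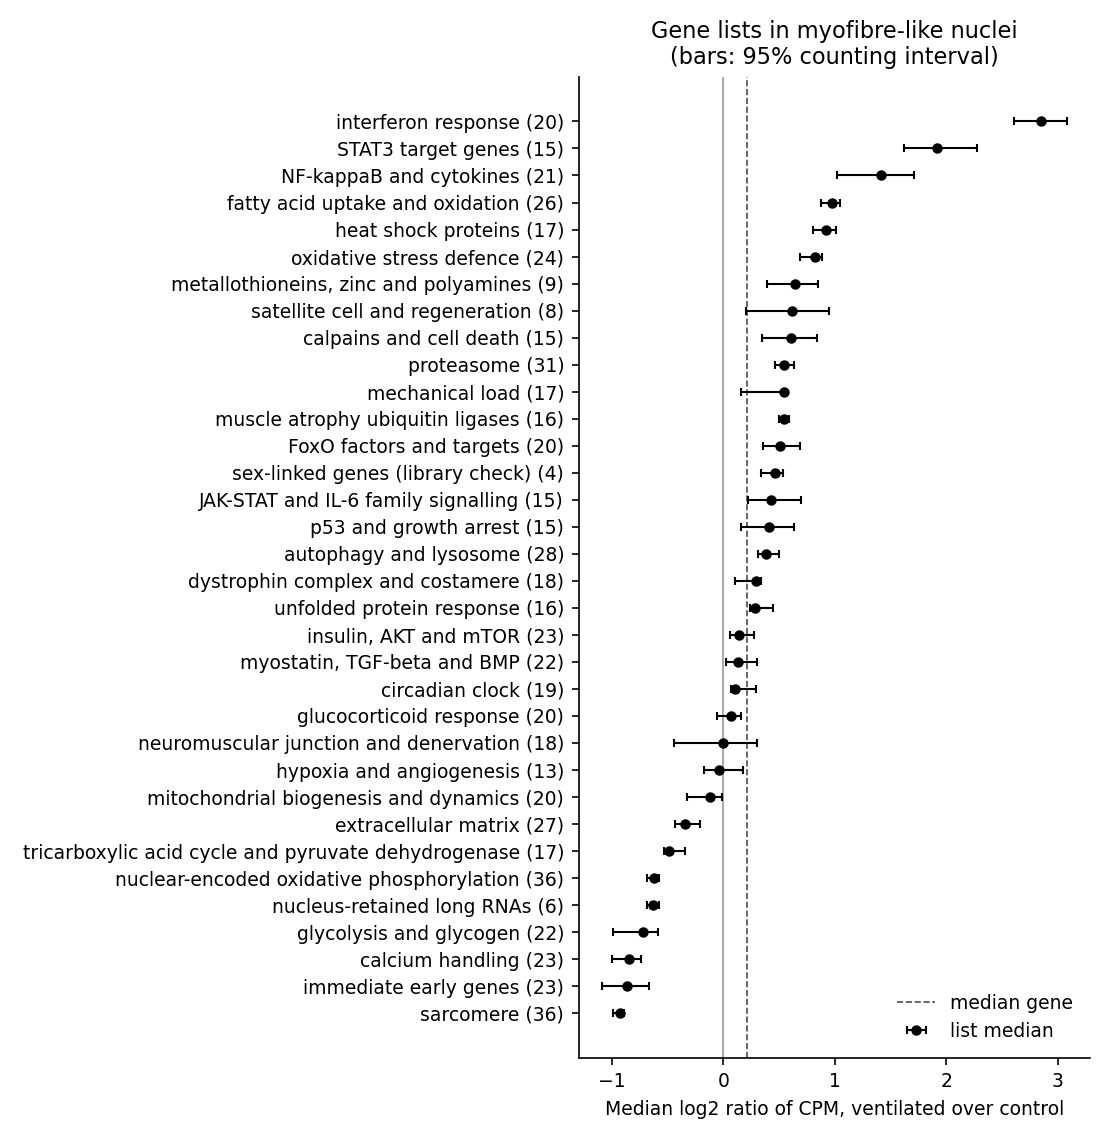
Points give the median log2 ratio of CPM (ventilated over control) for each gene list in myofibre-like nuclei, with bars for the 95% counting interval and the number of members measured in parentheses. The dashed line is the median gene at 0.21, the interferon response list lies at 2.85 and the sarcomere list at -0.92.

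Among single genes, the immunity-related GTPase gene Iigp1 (chromosome 18, 60376027 to 60392634) ranked highest by the fixed rule, with 5.61 and 650 CPM (ratio 116, 89.8 to 152). Its 2652 UMIs in ventilated nuclei came from 235 of 758 nuclei, with up to 83 in 1 nucleus. The acute-phase gene Serpina3n (0.644 and 82.8 CPM, ratio 129, 61.7 to 322), Cd274, which encodes the immune checkpoint ligand PD-L1 (1.56 and 127 CPM, ratio 81.0, 50.1 to 140), the serum amyloid gene Saa3 (3.22 and 117 CPM, ratio 36.4) and the interferon-induced GTPase gene Igtp (1.75 and 52.7 CPM, ratio 30.1) followed. Cemip, at 0.0920 and 24.8 CPM, and Saa3 were higher in ventilated mesothelial-like nuclei (273 and 276 CPM) than in myofibre-like ones, and Chl1 (0.828 and 30.4 CPM) reached 1456 CPM in the unnamed cluster. Iigp1 was higher too in ventilated mesothelial-like (771 CPM), unnamed (789 CPM) and lymphatic endothelial-like nuclei (834 CPM). Serpina3n, Cd274 and Igtp were lower in mesothelial-like nuclei (5.97, 79.7 and 44.2 CPM). The observed excess was 2.64 times that estimated from RNA of other classes for Iigp1 and 0.944 times for Saa3. Apart from Iigp1, Serpina3n, Cd274, Saa3 and Igtp, the higher genes came from few nuclei. Chl1 was found in 23 ventilated nuclei, with 67 of its 124 UMIs in 1 nucleus, and Cemip in 27, with 24 of 101 in 1. All 51 Cwh43 UMIs were in 1 ventilated nucleus, and those of Wincr1 (at least 59.5-fold higher, 0 control UMIs), Wdr95, Lexm and Cd109 were in 21, 21, 16 and 23 nuclei, almost all of those UMIs in clusters 7 and 8. Without these clusters the log2 ratios of Cwh43 and Cd109 were -0.48 and -1.71, and those of Wdr95 and Lexm 0.52 and 1.10, against 5.55 and 6.06 with them. The log2 ratios of Iigp1, Serpina3n, Cd274 and Chl1 were larger without these clusters, at 8.065, 8.251, 8.281 and 7.528, against 6.855, 7.006, 6.339 and 5.197 with them. Wincr1 then had 2 ventilated and 0 control UMIs, so its bound does not hold there.

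The orphan nuclear receptor gene Nr4a3 (chromosome 4, 48045153 to 48086447) stood at 41.3 and 0.980 CPM (ratio 0.0237, 0.00644 to 0.0612); its log2 ratio was -5.40, and -2.95 with called doublets kept. Rp1 (ratio 0.0651), Myom2, Tecrl (ratio 0.0727), Lgi1 (ratio 0.0719), Lrrc52 (ratio 0.0176, 0.000443 to 0.0997), Asb2, Slc41a3 (ratio 0.0490), Myh7b, a slow myosin gene (ratio 0.0565), Mettl21e (394 and 39.7 CPM, ratio 0.101), Ky (272 and 27.0 CPM, ratio 0.0990) and Alpl (ratio 0.0857) completed the 12. The log2 ratio of Lrrc52 was -5.83 as reported and from -6.60 to -3.14 under the alternatives, so it moved beyond its interval. Asb2, Mettl21e and Ky are also among the leading genes of cluster 0. That cluster held 68.1% of control and 3.17% of ventilated myofibre-like nuclei, and cluster 9 held 2.51% and 78.6%, so the libraries lay in different clusters of the class.

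**Figure D4:**
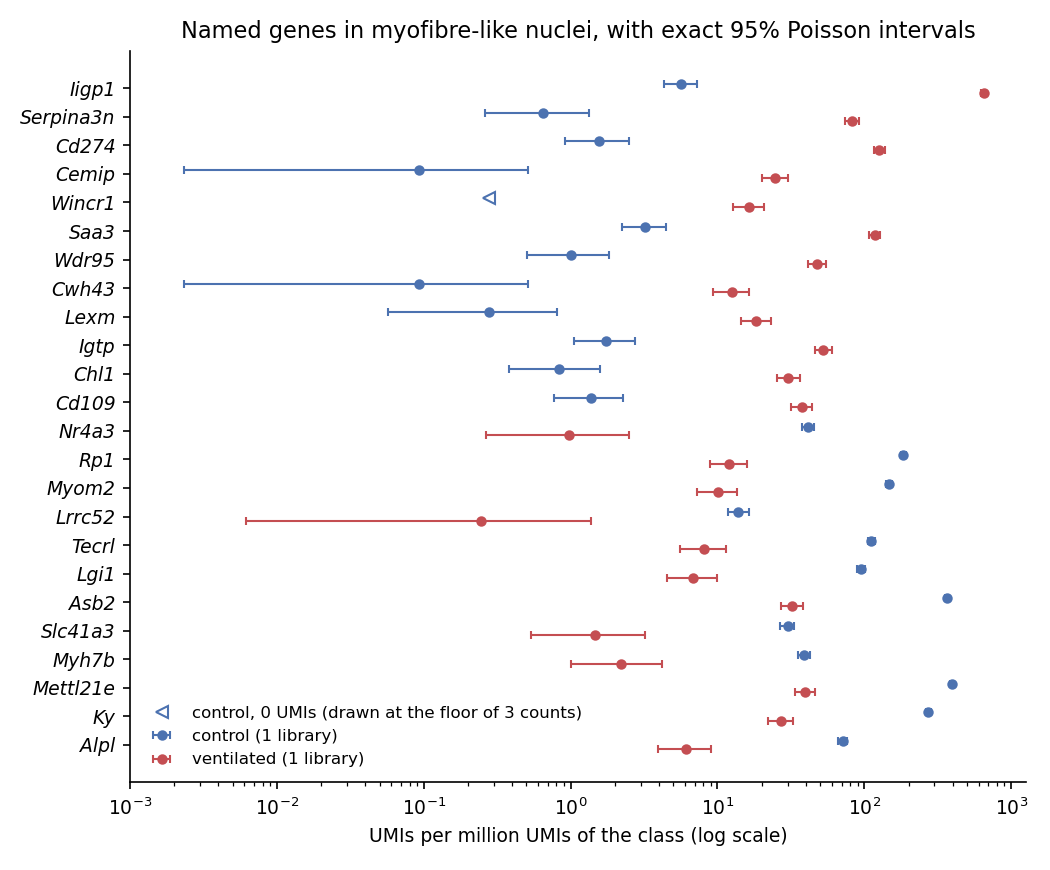
Points give the level of the 12 higher and 12 lower named genes in myofibre-like nuclei, in CPM on a log scale, with exact 95% Poisson intervals. The open triangle marks Wincr1 with 0 control UMIs at the floor of 3 counts, and Iigp1 stood at 5.61 CPM in control and 650 CPM in ventilated nuclei.

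Among nuclei with at least 2 UMIs of myosin heavy chain (Myh) genes, a gene dominated with at least 60% of them. By this rule the Myh1 and Myh2 shares were close. The Myh7 share was higher and the Myh4 share lower in the ventilated library, each with overlapping intervals. Myh1 (fast, type 2X) dominated in 59.0% of 2026 control and 55.7% of 494 ventilated nuclei (51.2 to 60.1), Myh2 (type 2A) in 26.1% and 27.3%, and Myh7 (slow) in 4.29% (3.45 to 5.27) and 7.29% (5.16 to 9.95). Myh4 (type 2B) dominated in 3.80% (3.01 to 4.73, 77 nuclei) and 2.23% (1.12 to 3.95, 11 nuclei). That ratio of 0.586 was 0.30 after thinning, with 3 ventilated nuclei. In 6.86% and 7.49% no gene dominated. The libraries differed in the nuclei with fewer than 2 Myh UMIs, which were 2.22% of control (1.63 to 2.95) and 34.8% of ventilated (31.4 to 38.3) myofibre-like nuclei, and 10.0% and 54.8% after thinning to 1000 UMIs. These nuclei are left out of the shares above, which therefore describe only nuclei with at least 2 Myh UMIs. Of all 2072 control and 758 ventilated myofibre-like nuclei, Myh1 dominated in 1195 and 275, Myh2 in 528 and 135 and Myh7 in 87 and 36. Cluster 6, led by Myh7, held 6.66% of control and 3.17% of ventilated myofibre-like nuclei. In 259 control and 71 ventilated nuclei the leading gene lay near the 60% limit, with 50% to 70% of Myh UMIs. The Myh1 transcript itself stood at 3947 and 1454 CPM (ratio 0.368, 0.358 to 0.379).

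Saa3 or Iigp1 was among the 5 higher named genes in each of the other compared classes. In fibro-adipogenic progenitor-like nuclei Saa3 (2.87 and 321 CPM, ratio 112, 47.0 to 350), the lysosomal channel gene Mcoln2 (ratio 79.9), Serpina3n (ratio 58.3), Iigp1 (ratio 22.0) and the metallothionein gene Mt2 (ratio 15.4) were higher. Thsd7b (ratio 0.0321, 0.00386 to 0.117), Nkain2 (ratio 0.0252), Adra1a (ratio 0.0393) and the matrix genes Col15a1 (374 and 40.1 CPM, ratio 0.107) and Aspn (ratio 0.167) were lower. At clustering resolution 2.0 this class held other nuclei, and the log2 ratios of Thsd7b, Nkain2 and Aspn were -1.24, -1.0 and -1.20, against -4.96, -5.31 and -2.58 as reported. Those of Serpina3n, Mcoln2 and Mt2 were then 3.52, 4.39 and 3.24, against 5.87, 6.32 and 3.94. For Nkain2 the value was also -1.41 with called doublets kept and -0.63 with an equal share of high-scoring nuclei left out. In lymphatic endothelial-like nuclei Gbp4 (6.05 and 232 CPM, ratio 38.4, 22.9 to 69.5), Saa3, Sh2d5, Mt2 and Iigp1 were higher, and Enkur, Thsd7b, Sez6l, Tgfb2 (272 and 34.0 CPM, ratio 0.125) and Tgfbi (ratio 0.108) were lower. The log2 ratio of Tgfb2 was -3.00 as reported and -2.18 with called doublets kept. Cluster 1 held 93.4% of the control and 26.6% of the ventilated nuclei of that class, and cluster 2 6.62% and 73.4%.

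In macrophage-like nuclei Acod1, the gene of the enzyme that makes itaconate (1.26 and 180 CPM, ratio 143, 25.1 to 5699), the signal-regulatory genes Sirpb1b and Sirpb1c, which are close paralogues (ratios 67.6 and 75.4), and Iigp1 (ratio 32.3) were higher. Colq, also one of the neuromuscular junction markers, had 0 control and 90 ventilated UMIs, at least 39.4-fold higher. Its log2 ratio was 7.89 as reported and from 5.25 to 7.91 under the alternatives, so the bound depended on the class limits. How many nuclei held the UMIs of a named gene was counted in myofibre-like nuclei only. Retnla, a marker of alternatively activated macrophages, was lower (104 and 1.65 CPM, ratio 0.0158, 0.000396 to 0.0905), as were Mamdc2, Wnt2 and Kcnq1 (log2 ratio -3.84, and -2.18 with called doublets kept). Myh4, a muscle gene, was also lower (90.6 and 4.95 CPM), in a class whose myofibre markers stood at 2485 and 758 CPM. Cluster 16, whose leading genes include Alox15 and Adgre1, held 51.8% of control and 23.1% of ventilated nuclei of this class, and cluster 4 the rest.

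In mesothelial-like nuclei Saa3 (2.81 and 276 CPM, ratio 98.0, 67.7 to 148), Cemip, which encodes a hyaluronan-degrading protein (3.11 and 273 CPM, ratio 87.5), and Pglyrp2 (0.100 and 31.9 CPM, ratio 318, 56.6 to 12580) were higher, as were Chl1 and Clec2g, at least 100-fold and at least 51.0-fold above 0 control UMIs. Cd248 (ratio 0.0711), the water channel gene Aqp5 (ratio 0.0629), Lgals7 (ratio 0.150), a gene with the symbol Ccl21a whose identifier is ENSMUSG00000094686 (ratio 0.130) and Krt19 (410 and 64.5 CPM, ratio 0.157, 0.145 to 0.170) were lower. Several genes share the symbol Ccl21a, so its value is uncertain, as are those of the serum amyloid, Gbp and Sirpb1 family genes, which have close copies. The Chl1 bound depended on the class limits, with 5 control UMIs and log2 ratios of 5.90 at clustering resolution 2.0 and 6.08 with at least 500 genes per nucleus. Clusters 10, 11 and 12 held most of the control nuclei (43.0%, 27.3% and 24.6%) and clusters 19, 20 and 21 most of the ventilated ones (19.4%, 27.2% and 28.2%), and Cemip and Pglyrp2 are among the leading genes of clusters 19 and 20.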

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

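Among the tests given here, those of RNA from other nuclei, of the procedures around ventilation, of a difference shared by all classes and of mesothelium alone were chosen only after the results were seen.

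The mechanical load list stood out because it lay on opposite sides of the median gene in myofibre-like and mesothelial-like nuclei. Relative to the median gene of each class its median log2 ratio was 0.34 in myofibre-like and -0.31 in mesothelial-like nuclei. The difference of 0.64 was not tested, since each group has 1 library. The list's median was -0.034 in nuclei dominated by Myh1 and 0.09 with control nuclei weighted to the ventilated mitochondrial share, both below the 0.21 of the median gene of myofibre-like nuclei.

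Interferon response genes and Stat3 were higher in ventilated myofibre-like nuclei. For Stat3 the excess over control was 5.20 times what RNA of the other classes, estimated from their markers, would give (6.27 and 3.02 with the lower and upper quartile of the marker estimates), which argues against such RNA as its whole source. For the interferon list that value was 1.03 (1.41 and 0.706 with the quartiles), for Cemip 0.457 and for the STAT3 target list 1.53 (2.06 and 0.962). RNA of other nuclei may therefore account for Cemip, for many interferon genes (3 of 20 were above 1.5, and 7 and 2 with the quartiles) and for part or all of the target list. The estimate is rough. It credits each class's markers in these nuclei in full to that class and adds the classes, although classes share markers. Fibro-adipogenic progenitor markers, for instance, stood at 2804 CPM in ventilated mesothelial-like and 812 CPM in ventilated myofibre-like nuclei. The same RNA can thus be counted under several classes, which would make the estimate too high and the values above too low. The estimate was above the whole ventilated level of some genes (Cemip 54.5 against 24.8 CPM, Oasl2 157 against 71.3 CPM) and below that of others (Gbp7 60.2 against 135 CPM). A value near 1 therefore does not show such RNA to be the source. Mixed nuclei stay open as well, since the test that left the same share out of each library (interferon median 3.23, against 2.85) left out 447 ventilated nuclei where the calls and filters left out 1212, which its bounds, written before the result, did not allow for. Effects of injection, anaesthesia or tracheostomy and of ventilation itself cannot be told apart, because 0 libraries are stated to have had these procedures without ventilation and the sources do not say whether the control animals had any of them.

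Sarcomere and oxidative phosphorylation genes were lower in ventilated myofibre-like nuclei, as was the mitochondrial share, which was lower in every other class too. With control nuclei weighted to a similar mitochondrial share (0.272% against 0.244%) the sarcomere median was -0.915, against -0.923 as reported. This lay past the bound written against less carried-over cytoplasm. The share rests on few UMIs per nucleus, with medians of 0.408% and 0.202% at median totals of 4077 and 4131 UMIs. The weighting may therefore not have matched the cytoplasm itself, and the test does not decide. With the same weighting the oxidative phosphorylation median was -0.48, between the bounds set for the test, so less carried-over cytoplasm stays open there too. A difference between the libraries shared by all classes may account for that list, whose medians in the 4 other compared classes had a median of -0.43. For sarcomere genes that median was -1.05, but RNA carried over from myofibres was estimated to give 1.18 times their control level there (median over classes, upper quartile of the markers), so it can follow from the pattern itself and decides nothing, which would hold for oxidative phosphorylation too with the highest marker (1.22 times) but not with the upper quartile (0.213).

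The myofibre-like share was lower in the ventilated library. With the same share of nuclei left out of each library the ratio was 0.627, against 0.490 as reported, so the doublet calls moved it and do not account for the whole difference. More mesothelium alone would leave the ratio of macrophage-like to fibro-adipogenic progenitor-like nuclei alike, and that ratio was 2.69 times as high in the ventilated library (2.13 to 3.39). It holds no myofibre-like nuclei and rests on a class that depended on the clustering, so it does not settle what lowered the myofibre-like share. Share ratios were 0.410 in fibro-adipogenic progenitor-like, 0.322 in satellite cell-like, 0.542 in endothelial-like, 0.574 in pericyte-like and 0.558 in adipocyte-like nuclei. They were 0.783 in lymphatic endothelial-like, 1.10 in macrophage-like, 2.23 in T or NK lymphocyte-like and 3.21 in B lymphocyte-like nuclei. How the samples were cut and how the nuclei were released was not tested and stays open, as does a biological difference.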

How the results depend on the processing

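The equal doublet removal (the 6% of nuclei with the highest scores left out of each library) and the removal of clusters 7 and 8 were chosen after the data were seen. With 1 library per group leaving out a library in turn was not possible and no paired analysis was possible. Of 240 alternative values of the named genes in myofibre-like nuclei 203 stayed within the reported counting interval, 35 moved beyond it and 2 changed direction. Of 442 list medians these were 295, 137 and 10 (12, 19 and 3 of them from scaling, which moves all genes alike and says nothing about single lists), and of 88 class share ratios 76, 12 and 0. For the values below the cause was not tested, except that scaling shifts all log2 ratios by the same amount and a pseudocount draws low genes toward 0.

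The mesothelial-like share ratio (1.49 as reported) was 1.77 with at most 1% mitochondrial UMIs, 1.39 with all barcodes, 1.38 with called doublets kept, 1.37 with centring within libraries and 1.42 with equal doublet removal. The myofibre-like ratio (0.490) was 0.431, 0.642, 0.620 and 0.627 with at most 1% mitochondrial UMIs, all barcodes, doublets kept and equal removal.

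Scaled to a median log2 ratio of 0, Stat3 was 2.12, oxidative phosphorylation -0.83, sarcomere -1.13, circadian clock -0.10, insulin, AKT and mTOR -0.067 and myostatin and TGF-beta -0.075. Without the 50 highest genes in the totals, oxidative phosphorylation was -0.69 and sarcomere -0.99. As a mean over nuclei, STAT3 targets were 2.35 and sarcomere -0.86. In nuclei dominated by Myh1, Stat3 was 1.98, STAT3 targets 1.37, oxidative phosphorylation -0.37, sarcomere -0.77, dystrophin complex -0.037 and mechanical load -0.034. With called doublets kept, Stat3 was 2.08 (1.37 in macrophage-like nuclei), oxidative phosphorylation -0.80, sarcomere -1.29, dystrophin complex -0.070 and extracellular matrix 0.12. With equal removal, Stat3 was 2.20, STAT3 targets 2.36, oxidative phosphorylation -0.81, sarcomere -1.28, interferon response 3.23, dystrophin complex -0.032 and extracellular matrix 0.30.

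With at least 500 genes per nucleus, oxidative phosphorylation was -0.72, sarcomere -1.06 and interferon response 3.12, and with at most 1% mitochondrial UMIs the interferon response was 3.08. Thinned to 1000 UMIs, STAT3 targets were 1.13 and sarcomere -0.88. Without clusters 7 and 8, Stat3 was 2.61, STAT3 targets 2.31, oxidative phosphorylation -0.78, sarcomere -1.04, immediate early genes 0.69, Cwh43 -0.48 and Cd109 -1.71. Over members with at least 100 UMIs, STAT3 targets were 0.61. With a pseudocount of 5 CPM, STAT3 targets were 1.09, oxidative phosphorylation -0.54, sarcomere -0.88 and interferon response 1.57. At resolution 2.0, Stat3 in fibro-adipogenic progenitor-like nuclei was 0.20.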

Other observations

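The gene lists were also computed in the other compared classes, a choice made after the data were seen. The interferon response list was higher in each of them, with median log2 ratios of 1.90 in fibro-adipogenic progenitor-like, 1.78 in lymphatic endothelial-like, 1.62 in macrophage-like and 1.51 in mesothelial-like nuclei, each at percentile 100 of matched lists. STAT3 target genes had medians of 1.11, 0.27, 1.17 and 1.23 in the same order, and NF-kappaB and cytokine genes 1.39, 0.68, 0.67 and 0.86. Neutrophil markers stood at 1.15 and 32.1 CPM (2 and 16 UMIs), 5.65 and 10.3, 147 and 279, and 1.00 and 5.62 CPM in these classes, and B lymphocyte markers at 13.8 and 72.3, 10.5 and 36.4, 562 and 286, and 11.2 and 25.6 CPM. RNA from other nuclei was estimated for the interferon, STAT3 target and cytokine lists in myofibre-like nuclei only.

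Oxidative phosphorylation genes had medians of -0.32, -0.27, -0.65 and -0.53 in these classes. Extracellular matrix genes had medians of -0.67, -0.32, -0.51 and -0.26 in the same order, and genes of p53 and growth arrest 0.38, 0.31, -0.27 and 0.67. List medians outside myofibre-like nuclei were not recomputed under the alternatives. The sarcomere list was lower in the other classes too, at -1.0, -0.94, -2.02 and -1.11. In macrophage-like nuclei 22 of 24 measured members were at least 1.5-fold lower and 0 higher. Tpm3, a member that cells outside muscle also use, fell outside the naming rule and stood at 294 and 327 CPM there.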
